A study of Mus musculus with 6 samples.

How the data were processed

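Pancreatic islets of virgin, pregnant and post-partum mice had been profiled by droplet single-cell RNA sequencing with unique molecular identifiers (UMIs, tags that mark each captured molecule). The series holds 6 libraries, 1 for each stage, and each was made from the pooled islets of several mice per the labels. The stages are Virgin, gestational days GD6.5, GD10.5, GD14.5 and GD18.5, and Pp4, day 4 after delivery. The time-point tag of the GD6.5 library reads GD6, and the name in its title was kept here. The deposited matrices hold the raw UMI count of each gene in each barcode, and Cell Ranger 7.1.0 wrote them per the file headers. The submitters' processing notes name the mouse genome build GRCm39. They give neither the annotation release nor the rule that chose the barcodes, and no other values of the series were used here. Genes are named by the symbols in the files, which list 33954 genes with 33916 different symbols. No coordinates are given, because the annotation at hand was of an earlier mouse build.

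The libraries held 59951 barcodes in all. Cells were kept with at least 500 genes and at most 15% of UMIs from mitochondrial genes. Doublets, droplets with more than 1 cell, were scored within each library by Scrublet in scanpy 1.11.5. The automatic score thresholds marked no Virgin cell and almost no Pp4 cell as a doublet. In their place the highest scores of each library were removed up to an expected share of 0.8% for each 1000 kept cells, a rule chosen after the data were seen. This left 46831 cells. Counts were log-normalised, 3000 variable genes were reduced to 40 principal components, and a graph of 15 neighbours was grouped by the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0), which gave 29 clusters. No correction between libraries was applied, since each library is both a stage and a batch.

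Clusters were named from 17 marker lists fixed before the data were examined, as were the cell filters, the clustering settings, the comparisons, the pathway lists and the rule for naming genes. A cluster took the name of the list with the highest mean score, and its cells are "beta-like", "alpha-like" and so on, written below as beta and alpha cells. The score thresholds were set after the data were seen. A name needed at least 3 detected markers, a score of at least 1.5 on the log2 scale and a lead of at least 0.5 over the next list. Clusters stayed unnamed if at least 50% of their cells were marked as doublets, if their 10 leading genes held more markers of another class, or if they had few UMIs and no marker among those genes. So did any cluster with a name outside the endocrine cells whose insulin transcripts exceeded 50% of the 90th percentile over clusters. This last rule removed the cluster, led by red cell markers, that held 46.1% of the Pp4 cells. Cells of the cluster led by G2/M genes took the class of their main hormone, or none if its level was low. Cycling was treated as a state of a cell and not as a type.

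Shares of cells carry exact Clopper-Pearson 95% binomial intervals. For gene levels, UMIs were summed over the cells of a class in a library and scaled to the same total in each class and library (CPM), with exact Poisson intervals. Ratios to Virgin are log2 ratios with a pseudocount of 1 CPM. The 95% intervals of single genes come from the exact conditional comparison of a pair of Poisson counts and belong to the ratio without a pseudocount, so for genes of low level in Virgin they can lie wholly beyond the printed value. These intervals cover counting error only. They hold no variation between cells, mice, islet isolations or libraries, so no gene was tested and no number of changed genes is given. The mean of the 4 gestational libraries against Virgin is a mean of log2 ratios, and its range is not a replicate error. Shares of cells with a given transcript were counted after each cell had been thinned at random to 3000 UMIs, and shallower cells were left out of those shares. A beta cell was called cycling when at least 2 of the 30 genes of the G2/M list were detected after thinning.

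For 20 fixed pathway lists, the median log2 ratio was taken over members with at least 5 CPM in the mean of the 6 libraries, where at least 3 members reached it. Its 95% interval comes from 2000 resamples of the members. Its percentile among 10000 random lists matched on level in 25 bins was also computed and is stated for some lists. Members of a list are not independent replicates, and both numbers describe these libraries only. Of the symbols in the lists, 10 were missing from the files. In alpha, delta, endothelial and macrophage cells the lists reported were mainly those with a result in beta cells or tied to the class. For some lists the values of these classes are set beside those of beta cells. The named genes of beta cells were the 8 highest and 8 lowest at each stage against Virgin, and the 10 highest and 10 lowest by the gestational mean with the same side in all 4 libraries. In the other 4 classes they were the 6 highest and 6 lowest by that mean. Ranking within a stage used the interval end nearest 0, and a gene needed 20 CPM in the higher library and at least 0.25 of its highest level in any other class there. Ribosomal, mitochondrial, haemoglobin and unnamed predicted genes were left out. A few genes that were measured are not reported here. List members and the genes Hbegf, Egfr, Kmt5a, Prlr, Tph1, Tph2, Ins1, Ins2 and Mki67 were reported besides.

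A family of 6 relations between the cycling share of beta cells and other measures was tested across the 6 libraries. Pearson and Spearman coefficients were given exact two-sided permutation p-values over all 720 pairings, adjusted within the family by the Benjamini-Hochberg method. Each alternative changed one step of the analysis, although the looser and stricter filters each changed several settings together. They covered a looser filter (200 genes, no mitochondrial limit, clustered again), a stricter filter (1000 genes, 10%), doublets kept, Leiden resolution 2, CPM without the islet hormone genes, median-of-ratios size factors, a pseudocount of 5 CPM, list minimums of 20 CPM and of none, thinning to 5000 UMIs, and 3 G2/M genes in place of 2. Added after the data were seen were Scrublet's automatic thresholds, the cells of the cluster led by G2/M genes, the gestational mean without GD18.5, and endothelial cells without a UMI of a pericyte marker. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9.

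The ratio and list methods were tested on simulated counts with the depths of the beta cells. The counts were drawn from the Poisson model on which the intervals rest, without variation between cells or libraries. Coverage near 95% was thus set by the design and checks the computation only. For GD14.5 against Virgin, 4601 genes were simulated and 200 of them changed. The 95% intervals covered the true log2 ratio in 95.8% of unchanged genes, in 97.0% of genes changed by 1 and in 96.0% of genes changed by 2. At the depths of Pp4 the shares were 94.6%, 94.0% and 95.0%. A list of 20 genes shifted by 0.5 was returned with a median of 0.50 at GD14.5 and 0.49 at Pp4. An unshifted list of 20 genes had a median of 0.01 at both, yet lay at percentiles 91.05 and 90.63 of the random lists. A high percentile alone is therefore weak evidence of a shift. In simulated cells of equal G2/M content with 6000 and 60000 UMIs, 87.3% and 100% met the cycling rule before thinning, and 52.0% and 51.9% after it.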

Results

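Islets were sampled at 6 stages around pregnancy in the mouse, with 1 library for each stage. The Virgin library held 9507 barcodes and 192038303 UMIs, GD6.5 held 9650 barcodes and 120301762 UMIs, and GD10.5 held 12724 barcodes and 135154739 UMIs. GD14.5 held 12492 barcodes and 143348501 UMIs, GD18.5 held 10945 barcodes and 143013139 UMIs, and Pp4 held 4633 barcodes and 68156173 UMIs. The median UMI count of a barcode was 19201 in Virgin, 11282 in GD6.5, 7776 in GD10.5, 8960 in GD14.5, 9676 in GD18.5 and 3599 in Pp4. After filtering and removal of doublets, 7762 cells of Virgin, 7783 of GD6.5, 9997 of GD10.5, 9737 of GD14.5, 8776 of GD18.5 and 2776 of Pp4 were used. Each stage was 1 library, so stage, mice, islet isolation and sequencing batch cannot be told apart. No difference between stages was tested, and intervals cover counting error only.

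The first comparison asked which cells the islet preparations held at each stage. Beta cells, which secrete insulin, were the largest class in Virgin, while alpha cells, which secrete glucagon, were the largest class in the 4 gestational libraries. Endothelial cells, which line the islet vessels, and macrophages, which take up debris and secrete growth factors, were both more frequent in the 4 gestational libraries and in Pp4 than in Virgin. Beta cells made up 66.3% of the used cells in Virgin (95% interval 65.3 to 67.4), 24.9% in GD6.5 (23.9 to 25.9), 26.8% in GD10.5 (25.9 to 27.6), 24.6% in GD14.5 (23.7 to 25.5), 23.3% in GD18.5 (22.4 to 24.2) and 17.4% in Pp4 (16.0 to 18.9). Among endocrine cells alone the beta share was 71.3% in Virgin, 28.5% to 30.9% in gestation and 41.4% in Pp4. Alpha cells made up 14.2% in Virgin, 29.6% to 36.1% in gestation and 12% in Pp4. Delta cells, which secrete somatostatin, made up 9.49% in Virgin, 20.5% to 23.0% in gestation and 8.86% in Pp4. Endothelial cells made up 1.55% in Virgin, 7.09% in GD6.5, 5.16% in GD10.5, 6.66% in GD14.5, 5.95% in GD18.5 and 4.57% in Pp4. Per 100 beta cells there were 2.33 endothelial cells and 0.97 macrophages in Virgin, against 19.3 to 28.5 endothelial cells and 7.17 to 10.4 macrophages in gestation. Pp4 held 26.2 endothelial cells and 9.30 macrophages per 100 beta cells. Dissociation frees cell types unequally, so these shares describe the suspensions and not the islets.

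The libraries differed in quality as well as in cell content. In Pp4, 47.6% of the used cells stayed without a class, nearly all of them in 1 cluster of barcodes with few genes that held haemoglobin and insulin transcripts. The unnamed share was 2.27% in Virgin and 1.30% to 2.84% in gestation. Beta cells of Pp4 had a median of 60597 UMIs, against 19051 to 24904 in the other libraries. Beta cells also grouped by library. In Virgin, 62.1% of them lay in 1 cluster and 27.6% in another, 57.7% of those of GD6.5 lay in a cluster of their own, and 79.5% of those of GD18.5 in yet another. GD10.5, GD14.5 and Pp4 shared a cluster with 52.3%, 59.7% and 51.2% of their beta cells. A cluster made mostly of 1 library may be that library and not a type of cell, so clusters were not compared with each other. Transcripts of acinar cells, which make digestive enzymes and leak RNA on dissociation, reached 1201 CPM in beta cells of Virgin and 14529, 10054, 6202 and 22784 CPM in those of GD6.5, GD10.5, GD14.5 and GD18.5. In Pp4 beta cells they reached 4786 CPM.

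The series title names beta cell proliferation, and the next comparison asked how many beta cells were in division at each stage. Genes of mitosis were higher than in Virgin in beta cells of all 5 other libraries. They included Mki67, which coats dividing chromosomes, Top2a, which untangles DNA, Cenpf and Cenpa, which act at the centromere, Cdk1, the kinase that starts mitosis, Ube2c, which marks cyclins for destruction, and Birc5, which guides chromosome separation. All 17 measured members of the G2/M list were higher in each of these libraries, and none was lower. Members of low level in Virgin passed the minimum level through the libraries where they were high, which favours such a count. With no minimum level the list median was smaller but still higher than in Virgin at each stage. The largest values lay at GD14.5, where Ube2c was higher by 4.73 on the log2 scale, Cenpf by 4.37, Cdk1 by 4.04, Birc5 by 4.04, Cenpa by 3.91, Top2a by 3.68 and Mki67 by 3.67. After thinning to equal depth, 0.28% of Virgin beta cells were cycling (14 of 5011, 95% interval 0.15 to 0.47). The share was 0.95% at GD6.5 (0.56 to 1.49), 3.55% at GD10.5 (2.86 to 4.35), 5.34% at GD14.5 (4.46 to 6.34), 2.84% at GD18.5 (2.16 to 3.67) and 1.77% at Pp4 (0.77 to 3.47). Without thinning the shares were 1.83%, 2.17%, 8.03%, 10.8%, 8.33% and 9.30% in the same order, and 139, 34, 169, 74, 35 and 33 beta cells were too shallow to be thinned. The summed G2/M transcripts were 22.9 CPM in Virgin, 90.3 at GD6.5, 231 at GD10.5, 517 at GD14.5, 248 at GD18.5 and 181 at Pp4.

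Alpha and delta cells were set beside beta cells as a background for free RNA from dividing cells. Alpha cells also held cells of the cluster led by G2/M genes, 7 in Virgin and 22 at GD18.5. Their share is thus not a measure of free RNA alone. Their cycling shares lay between 0.33% and 1.53% in alpha cells, with 0.95% in Virgin, and between 0.23% and 0.54% in delta cells outside Virgin. No Virgin delta cell of 715 was cycling, which allows a share of up to 0.42% by the floor of 3 counts, with an upper Clopper-Pearson limit of 0.51%. Endothelial cells were cycling at 2.63% in Virgin (3 of 114 cells), 0.99% at GD6.5, 1.90% at GD10.5, 3.75% at GD14.5, 3.92% at GD18.5 and 1.98% at Pp4. In macrophages the share was 2.13% in Virgin (1 of 47 cells), 8.33%, 8.06%, 11.2% and 6.38% in the gestational libraries, and 10.5% at Pp4.

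**Figure D1:**
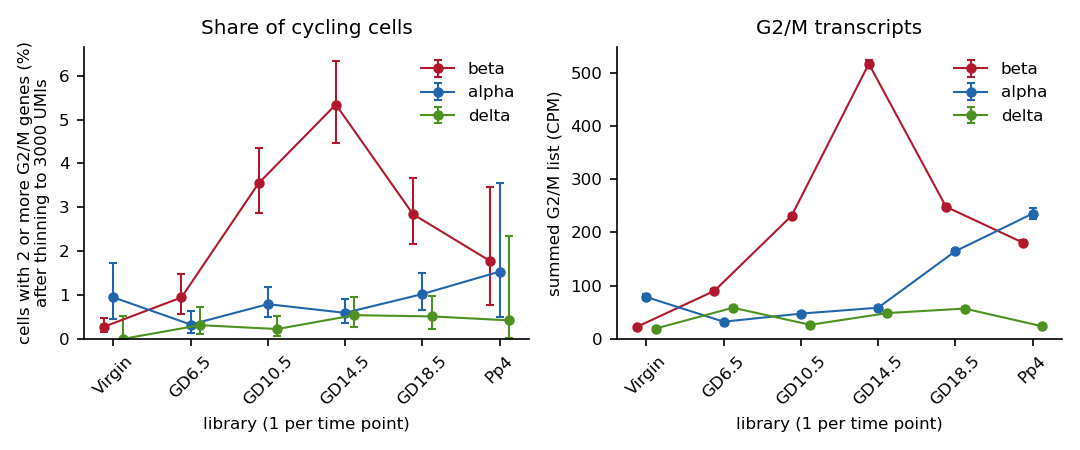
Share of cycling cells (%, left) and summed CPM of the G2/M list (right) in beta, alpha and delta cells of the 6 libraries, 1 point for each library, with 95% counting intervals as bars. The beta share is 0.28% in Virgin and 5.34% at GD14.5, while alpha cells stay between 0.33% and 1.53%.

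Beta cells of each later stage were then set against Virgin. The question was which known programs of pregnancy, such as the response to prolactin and placental lactogen, differed, and when. Scaling to total counts moved the median gene of beta cells by 0.17 at GD6.5, -0.13 at GD10.5, 0.01 at GD14.5, -0.05 at GD18.5 and -0.20 at Pp4 on the log2 scale. Changes smaller than about that size were given a direction only where they kept it under the other scalings, or the exception is named. The log2 values include a pseudocount of 1 CPM, so for genes near or below that level in Virgin they were smaller than the ratio of the counts. Cdk1, at 0.60 CPM in Virgin, stood at 4.04 at GD14.5, while the counting interval of its ratio ran from 5.08 to 5.75.

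At GD6.5 the prolactin program was not higher. Prlr, the prolactin receptor, and Cish, which prolactin signalling induces, were lower, at -0.70 and -0.52. Of the 17 measured members of the prolactin and serotonin list, 7 were higher, with a median of -0.04 (95% interval -0.34 to 0.20). This median lay at percentile 0.055 of the random lists, below nearly all of them. That was not particular to this list. Cholesterol synthesis (percentile 0) and the unfolded protein response (0.02) lay as low, while lists such as MHC class I (99.86) lay high. Tph1, which makes serotonin, had 2 UMIs in all Virgin beta cells and 0 at GD6.5, so no ratio is given. The genes that stood highest were the metallothioneins Mt2 (1.96) and Mt1 (1.69), which bind zinc and respond to stress and glucocorticoids, the histone gene H2ac18 (1.93), Syt16 (1.75), a relative of the calcium sensors of secretion, the splicing factor Rbfox1 (1.54), the peptidase Anpep (1.52), the ribonuclease Rnase4 (1.49) and the small GTPase Rit2 (1.48). Lowest were Cox6a2, a respiratory chain subunit (-2.14), the transcriptional cofactor Fhl2 (-1.35), the chaperones Hsph1 (-1.33) and Dnaja1 (-0.92), Pde10a, which breaks down cyclic nucleotides (-1.31), the stress gene Trp53inp1 (-1.13), the clock gene Per2 (-0.92) and Herpud1, which clears misfolded proteins (-0.90). Insulin transcripts were lower as well, with Ins1 at -0.30 and Ins2 at -0.23.

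At GD10.5 the prolactin program was higher in 14 of 17 members, with a median of 1.11 (0.15 to 2.09). Prlr stood at 982 CPM against 455 in Virgin, a ratio of 2.16 (95% interval 2.13 to 2.18). Tph1 stood at 14.95 CPM with 796 UMIs against 2 UMIs in Virgin, and its counting interval allowed ratios from 280 to 8406. Other genes that stood highest were Fmo1, a detoxifying oxidase (3.80), Cenpf (3.74), Lockd, a transcript beside a cyclin inhibitor gene (3.46), Neb, a giant actin-binding protein (3.21), Stmn1, which destabilises microtubules (2.91), Chgb, a protein of the insulin granule (2.49), Ivd, which breaks down leucine (2.30), and the transcription factor Ovol2 (1.96). Tph2, another serotonin enzyme, was higher by 2.47, Matn2, a matrix protein, by 2.09, and Cish by 2.02. Lowest were Fhl2 (-2.34), Hsph1 (-1.78), Baiap2, which shapes the actin skeleton (-1.75), Per2 (-1.69), Pde10a (-1.69), Rgs2, which dampens G protein signals (-1.61), Trp53inp1 (-1.56) and the clock gene Cry2 (-1.48). Of the insulin genes, Ins1 was higher by 0.32, and Ins2 stood at -0.07, a sign that flipped under median-of-ratios scaling.

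At GD14.5 the prolactin list had its largest median, 2.09 (0.13 to 3.09), with 15 of 17 members higher. Tph1 reached 25.1 CPM with 1311 UMIs, and Tph2 reached 18.6 CPM against 1.01 in Virgin. Fmo1 was higher by 5.23. Cldn8, which seals cell junctions, stood at 42.9 CPM against 7 UMIs in Virgin and Sftpd, a secreted lectin, at 29.1 CPM against 9 UMIs. With the pseudocount they were higher by 5.38 and 4.82, below their counting intervals of 8.66 to 11.02 and 7.85 to 9.91. Neb stood at 4.31, Lrrc55, a regulator of potassium channels, at 4.26, Matn2 at 3.09, Ivd at 3.09, Chgb at 2.92, Ehhadh, which oxidises fatty acids, at 2.75 and Wipi1, which acts in autophagy, at 1.73. The unfolded protein response, which restores protein folding in the endoplasmic reticulum, was higher in 20 of 21 members with a median of 0.36 (0.20 to 0.59), among them Sdf2l1 (1.28) and the secreted factor Manf (0.63). At GD14.5 it was also higher in endothelial cells (0.26, 0.10 to 0.37, 18 of 22), while its intervals in alpha, delta and macrophage cells included 0. Of the S phase list, which covers DNA replication, all 5 measured members were higher in beta cells, with Tyms, which makes thymidylate, at 0.92 and a list median of 0.51 (0.47 to 0.92). The growth regulator Myc was higher by 1.79 and the cyclin kinase inhibitor Cdkn2c by 1.99, while Ccnd2, the main D cyclin of beta cells, was lower at -0.91. Lowest were Rgs2 (-2.03), Pde10a (-1.95), Baiap2 (-1.90), Mdm1, a microtubule protein (-1.88), Fhl2 (-1.82), Cib3, a calcium-binding protein (-1.78), Hsph1 (-1.70) and the transcription factor Sox4 (-1.69).

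At GD18.5 Lrrc7, a scaffold protein of synapses, stood at 104 CPM against 0.60 in Virgin, higher by 6.03. Cldn8 (4.8), Neb (4.67), Cenpf (3.73), Ube2c (3.65), Fmo1 (3.59), Lockd (3.12) and Ogdhl, a mitochondrial enzyme of glutamate use (3.12), followed. The prolactin list stood at 1.41 (0.14 to 2.66), with 14 of 17 members higher, although Prlr stood at 0.15. Of the identity and glucose-sensing list, which holds the hormones, transcription factors and channels of mature beta cells, 5 of 27 members were higher, and the median was -0.20 (-0.46 to -0.09). The list was not lower in beta cells alone. At GD18.5 the list stood at -0.21 in alpha cells (-0.44 to -0.08, 6 of 26 higher) and -0.22 in delta cells (-0.39 to -0.12, 6 of 26). It stood at -1.14 in macrophages and 0.67 in endothelial cells. Free beta cell RNA was not told apart from expression in these other classes. Ins2 made up 30.0% of all UMIs in the Virgin library and 13.3% in that of GD18.5. The values of the other classes thus do not show whether the change in beta cells was shared. In beta cells Ucn3, a marker of mature beta cells, stood at 79.1 CPM against 172, and the glucose transporter Slc2a2 at -0.77. Lowest were Hsph1 (-1.99), the membrane protein Sgcz (-1.80), Cox6a2 (-1.75), Scd2, which desaturates fatty acids (-1.66), Cib3 (-1.44), Dnaja1 (-1.43), Fhl2 (-1.40) and Phactr1, a regulator of actin (-1.37). This library also carried the most acinar RNA in beta cells.

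At Pp4, after delivery, much of the program was still higher than in Virgin. The prolactin list stood at 1.5 (0.38 to 2.10), with 16 of 17 members higher, and Prlr at 0.59. Fmo1 (3.78), Neb (3.26), Cenpf (3.07), Matn2 (2.91), Myo3a, a motor protein (2.33), Taco1, which aids mitochondrial translation (2.29), the neuropeptide Npy (2.16) and Ovol2 (2.08) stood highest. Lowest were Pde10a (-1.94), Fhl2 (-1.88), Rgs2 (-1.78), the deubiquitinase Usp51 (-1.61), Hsph1 (-1.59), Per2 (-1.59), Dnaja1 (-1.55) and Baiap2 (-1.52). Ins1 was higher by 0.50, and Ins2, at 0.003, had no direction that held under the other filters. These values rest on 484 beta cells of unusual depth.

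**Figure D2:**
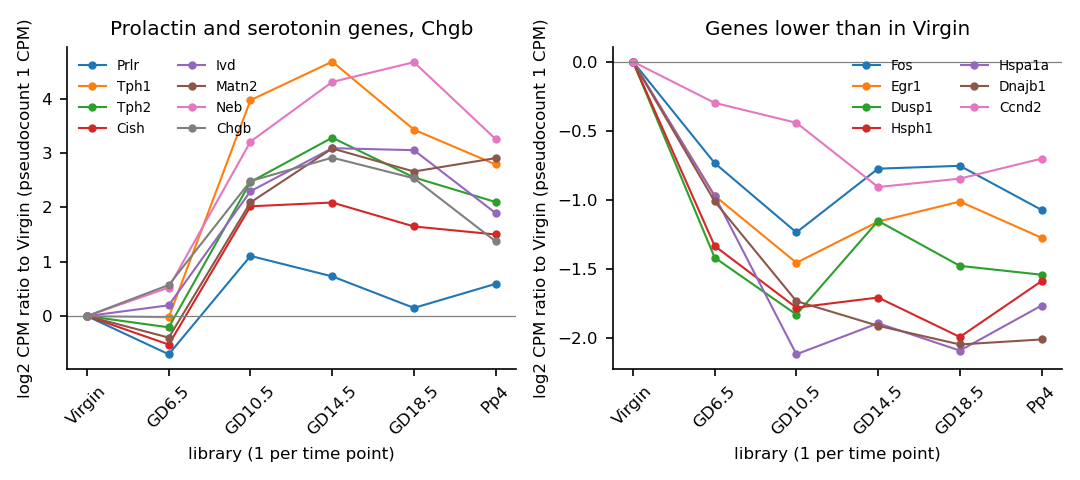
Log2 CPM ratio to Virgin of genes of the prolactin and serotonin list with Chgb (left) and of genes lower than in Virgin (right) in beta cells, 1 point for each library. Prlr stands at -0.70 at GD6.5 and 1.11 at GD10.5, while Hsph1 lies between -1.33 and -1.99 in all 5 libraries.

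Genes were then ranked by the mean of the 4 gestational libraries, among those on the same side of Virgin in all 4 that reached the level needed for naming in each comparison. Genes of low level in Virgin and GD6.5, such as Cenpf, dropped out of this ranking. Its highest genes were Ivd (2.16), Chgb (2.13), Ogdhl (1.66), the G protein subunit Gnai1 (1.42), the carbonic anhydrase Car15 (1.25), the inositol transporter Slc2a13 (1.23), the activin receptor Acvr1c (1.13), the adhesion protein Amigo2 (1.12), the mitochondrial protein Smim26 (1.11) and Ost4, which helps attach sugars to proteins (1.06). Ivd stood at only 0.20 at GD6.5, where its sign flipped without hormone genes in the total. The lowest were Fhl2 (-1.73), Hsph1 (-1.70), Pde10a (-1.34), Baiap2 (-1.34), Per2 (-1.28), Rgs2 (-1.26), Cox6a2 (-1.26), Dnaja1 (-1.17), Dnaja4, another chaperone (-1.13), and Trp53inp1 (-1.12). Early response and heat shock genes, which cells switch on within minutes of a stimulus or of dissociation, formed the lowest list. Of its 20 measured members 2 were higher, with a median of -1.02 (-1.32 to -0.72) that lay below all random lists, and Dusp1, Fos, Jun, Egr1, Hspa1a and Dnajb1 were lower in each of the 5 libraries. Hspb1, a small heat shock protein, was higher in all 4 gestational libraries. Genes of cholesterol synthesis were lower in 13 of 14 members, with a median of -0.57 (-0.70 to -0.21). Nuclear genes of oxidative phosphorylation were higher in 31 of 31 members, with a median of 0.32 (0.26 to 0.41), a direction that flipped at GD6.5 without hormone genes in the total and under median-of-ratios scaling. The mitochondrially encoded genes of the same complexes stood at -0.21 (-0.34 to -0.10), with 2 of 13 higher, although at GD6.5 12 of 13 were higher (0.20), a sign that flipped without hormone genes in the total. The mean was also lower in macrophages (-0.31, -0.50 to -0.20) and delta cells (-0.09, -0.11 to -0.02), while the intervals of alpha and endothelial cells included 0. At GD10.5 this list stood at -0.55 in beta, -0.30 in delta, -0.20 in endothelial cells, -0.71 in macrophages and 0.06 in alpha cells, so its shift was not particular to beta cells.

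Genes of antigen presentation and of the interferon response were higher at GD6.5 and GD14.5, while at GD10.5 and GD18.5 the intervals of both lists included 0. In the gestational mean the MHC class I list had 9 of 10 members higher and a median of 0.33 (0.19 to 0.70), and the interferon list had 7 of 7 members higher and a median of 0.21 (0.10 to 0.55). B2m, the light chain of MHC class I, was higher by 1.40 at GD6.5, 0.59 at GD10.5, 1.13 at GD14.5 and 1.05 at GD18.5. The REG family, secreted proteins of stressed acinar and islet cells, had 4 of 4 members higher with a median of 3.90 (2.48 to 4.47). Reg1 stood at 46.5 CPM in Virgin and at 984 CPM at GD18.5, and Reg2 and Reg3b moved with it. REG genes were also higher in alpha, delta, endothelial and macrophage cells and, like the acinar RNA, were highest at GD18.5 and lowest in Virgin, so free RNA was not told apart from expression. In the list of macrophage activation, 2 of 3 measured members were higher in beta cells, with a median of 1.64 (-0.08 to 2.18), beside macrophage markers of 43.0 CPM in Virgin beta cells and 31.7 to 156 CPM in gestation. For 7 other lists the interval included 0. They were the identity and glucose-sensing list (-0.07, 10 of 27 higher), the unfolded protein response (0.11, 13 of 21), the G1 cyclins and CDK inhibitors (-0.01, 5 of 12), H4K20 methylation (-0.04, 3 of 7), polyamine, amino acid and one-carbon metabolism (0.13, 7 of 13), angiogenesis (0.21, 2 of 3) and endothelial growth factors and matrix (0.05, 3 of 5). Stages went opposite ways beneath some of these means. The unfolded protein response stood at -0.08 at GD6.5 and 0.36 at GD14.5, the polyamine list at 0.21 at GD14.5 and -0.13 at GD18.5, and H4K20 methylation at 0.17 at GD6.5, a sign that flipped without hormone genes, and -0.18 at GD10.5. The mean of the S phase list (0.16, 0.04 to 0.25), at percentile 85.7 of the random lists, rested on GD14.5. At GD6.5 (0.12, 4 of 5 higher), GD10.5 (-0.01, 2 of 5) and GD18.5 (-0.15, 1 of 5) its intervals included 0. The prolactin list stood at 1.0 (0.08 to 2.03), with 15 of 17 members higher. Without a pseudocount, and with Tph1 in Virgin set to the floor of 3 UMIs, it stood at 0.84. In that median Tph1 ranked lowest because it had 0 UMIs at GD6.5, so 0.84 does not show the effect of the floor alone. The G2/M list stood at 2.57 (2.31 to 2.69).

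**Figure D3:**
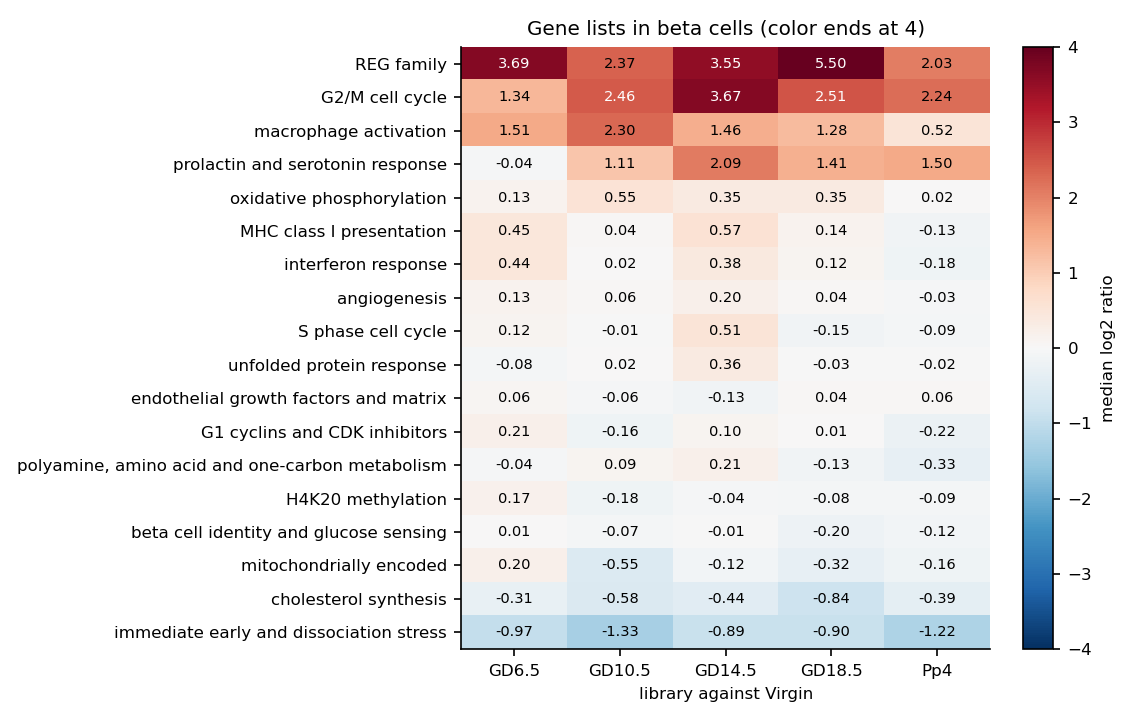
Median log2 CPM ratio to Virgin of each gene list in beta cells, with libraries as columns and lists as lines of the map, and with color from blue (lower) to red (higher). The G2/M list ranges from 1.34 to 3.67, the early response and stress list from -0.89 to -1.33, and the oxidative phosphorylation value at GD6.5 (0.13) flips under other scalings.

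The series title traces beta cell proliferation to HBEGF, an EGF family growth factor, from endothelial cells, and to its receptor EGFR and the histone methyltransferase Kmt5a in beta cells. The next comparison asked where and when the transcripts of these genes were found. Transcript levels do not measure the release of HBEGF, the activation of EGFR or the activity of the Kmt5a enzyme. Hbegf was a gene of endothelial and ductal cells. Among endothelial cells it stood at 389 CPM in Virgin (95% interval 355 to 425), 257 at GD6.5 (241 to 273), 381 at GD10.5 (360 to 404), 355 at GD14.5 (338 to 372), 278 at GD18.5 (263 to 294) and 295 at Pp4 (269 to 323). The gestational mean was -0.31 against Virgin (-0.44 to -0.17), and GD10.5, the highest gestational library, lay within the interval of Virgin. After thinning, 53.5% of endothelial cells in Virgin had an Hbegf UMI, against 44.1%, 59.4%, 56.7% and 46.8% in gestation and 37.6% at Pp4. In macrophages, which served as background, the share was 0% to 3.19%, at median depths of 6205 to 20250 UMIs against 5022 to 9485 in endothelial cells. In ductal cells Hbegf stood at 809.5, 1229, 947, 591 and 1284 CPM in Virgin, GD6.5, GD10.5, GD14.5 and GD18.5, and Pp4 held too few ductal cells for a level. Gamma cells, which secrete pancreatic polypeptide, stood at 42.3 to 57.0 CPM, pericytes at 30.2 to 72.6 CPM and beta cells at 3.87 to 8.69 CPM. Of all Hbegf UMIs in used cells, endothelial cells held 17.1% in Virgin, 27.2% at GD6.5, 40.3% at GD10.5, 51.4% at GD14.5, 33.1% at GD18.5 and 39.1% at Pp4. In Virgin beta cells held the largest part, 42.1%, against 5.75% to 8.97% in the other libraries, and at GD6.5 ductal cells held 32.7%, more than endothelial cells. These shares depend on the number of cells captured of each class as well as on the level per cell.

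Egfr was higher in beta cells than in alpha cells. It stood at 31.7 CPM in Virgin beta cells, 29.8 at GD6.5, 22.6 at GD10.5, 22.8 at GD14.5, 27.3 at GD18.5 and 30.3 at Pp4, against at most 1.23 CPM in alpha cells. The gestational mean was -0.31 (-0.36 to -0.25). The share of beta cells with an Egfr UMI after thinning lay between 6.85% and 9.09%, against 0% to 0.28% in alpha cells. Fibroblasts, where present, stood at 86.1 to 311 CPM. Kmt5a, which places the first methyl group on lysine 20 of histone H4, was lower in beta cells than in alpha and delta cells in all 6 libraries. In beta cells it stood at 16.6 CPM in Virgin, 20.9 at GD6.5, 19.99 at GD10.5, 19.0 at GD14.5, 16.9 at GD18.5 and 18.2 at Pp4, a gestational mean of 0.19 (0.12 to 0.26). Among beta cells not called cycling, a set chosen after the data were seen, it stood at 16.4 CPM in Virgin and 19.8, 18.2, 14.6 and 14.7 CPM in gestation, so the higher mean did not hold there at GD14.5 and GD18.5. In alpha cells it stood at 54.7, 65.4, 76.0, 72.5, 48.1 and 54.2 CPM, and in delta cells at 48.6, 57.2, 70.7, 61.8, 46.2 and 56.6 CPM. Among other ligands, Tgfa and Btc were highest in ductal cells, at 26.1 to 54.9 and 12.7 to 40 CPM, and Egf stood at 7.1 to 14.0 CPM in beta cells. The receptors Erbb4 and Erbb3 were highest in ductal cells, at 233 to 707 and 74.9 to 150 CPM. The 10 Schwann cells of GD6.5, with 1 UMI of Btc and 9 of Erbb3, were too few to be ranked against ductal cells, and so were the fibroblasts for Btc in Virgin and GD6.5. Fewer than 3 members of the EGF ligand and receptor lists reached the minimum level in beta cells, so neither list has a median there.

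**Figure D4:**
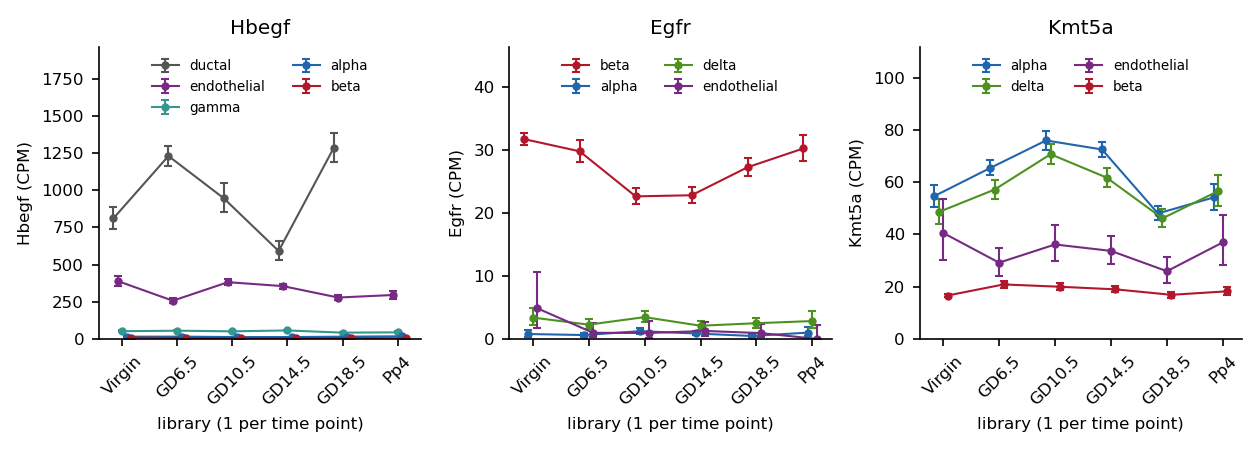
CPM of Hbegf (left), Egfr (middle) and Kmt5a (right) by cell class in the 6 libraries, with exact Poisson 95% intervals as bars. Endothelial Hbegf stands at 389 CPM in Virgin and at 257 to 381 CPM in gestation, and beta cell Egfr at 31.7 CPM in Virgin and 22.6 CPM at GD10.5.

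Across the 6 libraries, 6 measures were related to the cycling share of beta cells by exact two-sided permutation tests. Beta cell Tph1 gave r = 0.991 (exact p = 0.00278, the smallest that 720 pairings can give, adjusted 0.0167) and rho = 0.943 (exact p = 0.0167, adjusted 0.1), with r = 0.992 without the 2 libraries farthest from the median. Beta cell Egfr gave r = -0.925 (exact p = 0.0111, adjusted 0.0333) and rho = -0.886 (exact p = 0.0333, adjusted 0.1), with r = -0.915 without 2 libraries. The adjusted p of Egfr was 0.0583 under the looser filter and 0.258 without hormone genes in the total. Beta cell Prlr gave r = 0.682 (exact p = 0.135, adjusted 0.269) and rho = 0.829 (exact p = 0.0583, adjusted 0.117), with r = 0.729 without 2 libraries. Endothelial Hbegf gave r = 0.218 (exact p = 0.683, adjusted 0.688) and rho = 0.029 (exact p = 1, adjusted 1), with r = 0.643 without 2 libraries. Kmt5a in beta cells gave r = 0.199 (exact p = 0.688, adjusted 0.688) and rho = 0.314 (exact p = 0.564, adjusted 0.677), with r = 0.424 without 2 libraries. The endothelial share of cells gave r = 0.538 (exact p = 0.278, adjusted 0.417) and rho = 0.371 (exact p = 0.497, adjusted 0.677), with r = 0.845 without 2 libraries. Each library is a batch of its own, so no relation across stages could be computed within batches. Cycling and other beta cells of the same library are compared in the closing section.

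Alpha cells were compared in gestation against Virgin to see which changes reached beyond beta cells. In alpha cells the clock genes Per2 (-1.62), Nr1d2 (-1.58), Per3 (-1.55) and Tef (-1.19), Ppargc1a, which drives mitochondrial genes (-1.12), and the signalling regulator Tmem131l (-1.08) were lowest. Highest were Ddah1, which degrades an inhibitor of nitric oxide synthesis (1.32), the host transcripts of small nucleolar RNAs Snhg6 (1.11) and Snhg8 (0.97), the methyltransferase Etfbkmt (1.10), Pdk4, which spares glucose for fat oxidation (1.03), and the respiratory subunit Sdhd (0.98). The prolactin list was not higher in alpha cells (median -0.01, 6 of 12 members higher), nor were the early response genes lower in the mean (0.00, 11 of 22 higher), although they were at GD10.5 (-0.19) and at Pp4 (-0.44, 3 of 22 higher). MHC class I (0.38, 11 of 11), interferon (0.52, 8 of 10), oxidative phosphorylation (0.16, 29 of 31) and REG genes (2.90, 5 of 5) were higher. Cholesterol synthesis stood at -0.03 (7 of 15 higher) and H4K20 methylation at -0.23 (-0.33 to -0.05, 1 of 8 higher). The G2/M list had no common direction. It stood at -1.25 at GD6.5 (0 of 7 higher), -0.57 at GD10.5, -0.62 at GD14.5, 0.84 at GD18.5 (0.24 to 1.43, 7 of 7) and 1.41 at Pp4 (7 of 7), with a gestational mean of -0.36. Scaling moved the median alpha cell gene by -0.15 at GD6.5 and GD18.5 and by less at the other stages. At resolution 1 alpha cells lay mainly in a pair of clusters that all libraries shared. The first held 75.7% of Virgin alpha cells and 26.2% to 49.8% of those in gestation, and the other 21.6% and 37.2% to 67.7%. At resolution 2 some alpha clusters followed the libraries. In 1 of them 783 of 834 cells were from Virgin. Another, with Pdk4 among its leading genes, held 1290 cells of GD18.5, 713 of GD6.5 and 6 of Virgin. The alpha cell changes are thus also bound to library.

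Delta cells shared with beta cells the lower early response genes. All 22 measured members were lower, with a median of -0.94 (-1.19 to -0.69), among them Jun at 1827 CPM in Virgin and 853 to 1041 CPM in gestation and Egr1 at 1128 and 411 to 586 CPM. Delta cells lay in a pair of clusters whose shares differed as well. The first held 81.3% of Virgin delta cells and 42.8% to 67.7% of those in gestation, and the other 18.7% and 32.3% to 57.0%. Lowest were Fhl2 (-2.08), Ppargc1a (-2.08), the adhesion protein Vcl (-2.07), the clock gene Arntl (-1.92), the insulin receptor substrate Irs2 (-1.86) and Ccdc141, which acts in cell migration (-1.71). Highest were Smim26 (1.05), Anpep (1.03), the splicing protein Snrpf (0.98), Ost4 (0.95), the copper chaperone Cox17 (0.91) and the imprinted gene Peg10 (0.89). MHC class I (0.38, 11 of 11), interferon (0.51, 13 of 15), oxidative phosphorylation (0.29, 31 of 31) and REG genes (3.13, 5 of 5) were higher. The prolactin list stood at -0.08 (6 of 13 higher), cholesterol synthesis at -0.16 (6 of 18 higher) and H4K20 methylation at -0.27 (-0.34 to -0.11, 1 of 8 higher), and fewer than 3 G2/M genes reached the minimum level. The S phase list stood at -0.04 (3 of 9 higher), with an interval that included 0. B2m stood at 19.3 CPM in Virgin delta cells and 35.6 to 68.2 CPM in gestation, and in alpha cells at 18.8 and 41.7 to 60.7 CPM.

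Endothelial cells were of interest as the named source of HBEGF. Sox18, a transcription factor of vessel growth, was higher in gestation (1.31), as were Snhg6 (2.03), Hrct1, a small membrane protein (1.57), Gda, which degrades guanine (1.55) and the MHC gene H2-Q6 (1.43). Lowest were Stab2 (-4.66), Pld5 (-3.74), Lyve1 (-3.59), Kcnj8 (-3.15), Cd248 (-3.11) and the clock gene Dbp (-3.09). The first 3 of these, of which Stab2 and Lyve1 mark sinusoidal and lymphatic vessels, were higher in gestation at resolution 2. Kcnj8 and Cd248 are pericyte genes, and 40.8% of Virgin endothelial cells held a UMI of a pericyte marker, against 7.17% to 9.72% in gestation and 15.0% at Pp4. Angiogenesis genes showed no common direction (median -0.16, 7 of 17 higher), although Esm1, which marks sprouting vessels, stood at 2867 CPM in Virgin and 4696 CPM at GD14.5, and Apln, a peptide of tip cells, at 40.6 and 105 CPM. The main VEGF receptor, Kdr, stood at 3298 CPM in Virgin and 3401 to 4258 CPM in gestation. Growth factors and matrix stood at -0.13 (9 of 19 higher), H4K20 methylation at -0.34 (0 of 8 higher), early response genes at -0.03 (9 of 22 higher, but -0.44 with 4 of 22 at Pp4) and the prolactin list at -0.22 (4 of 11). G2/M and interferon genes went opposite ways by stage. G2/M stood at -1.52 at GD6.5 (1 of 19 higher), -0.59 at GD10.5 and 0.68 at GD14.5 (14 of 19), and interferon at 0.70 at GD6.5 (21 of 24) and -0.59 at GD18.5 (6 of 24), beneath means of -0.39 and -0.03. The S phase list did not follow G2/M at GD14.5, where it stood at -0.41 (3 of 10 higher) with an interval that included 0. It was lower at GD6.5 (-0.90), GD10.5 (-0.63), GD18.5 (-0.82) and Pp4 (-0.54), with a gestational mean of -0.68 (-1.02 to -0.23). MHC class I stood at 0.27 (9 of 12), with an interval that included 0. Higher lists were cholesterol synthesis (0.26, 11 of 14), oxidative phosphorylation (0.17, 24 of 31) and REG genes (2.94, 5 of 5). The Virgin class held 120 cells, with haemoglobin and other red cell transcripts at 881 CPM, against 1.95 to 2447 CPM in gestation and 9978 CPM at Pp4. Scaling moved the median endothelial gene by -0.18 at GD18.5 and -0.11 at Pp4. At resolution 2 a cluster led by Glycam1 and Fabp4 scored highest for endothelial markers but stayed unnamed, as red cell markers led it. With doublets counted, it held 408 cells of GD18.5 and 72 of GD14.5. The largest endothelial cluster, led by Esm1, held 197 and 658. Endothelial values at GD18.5, Hbegf among them, may thus reflect a different mix of endothelial cells.

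In macrophages, genes of the cell cycle were higher in gestation. Top2a had 0 UMIs in the 50 Virgin macrophages and 60 to 169 UMIs in each gestational library, and Stmn1, with 2 UMIs in Virgin, was 37.1-fold higher at GD14.5 (95% interval 10.2 to 308). All 27 measured G2/M genes were higher in gestation, with summed levels of 105 CPM in Virgin and 369 to 773 CPM in gestation. The median log2 ratio was 3.30, but 18 of these genes had no Virgin UMI and 24 had at most 3. The 18 passed the minimum level through the other libraries only, which favours a count on the higher side. The 24 were then bounded by the floor. With the Virgin counts of these 24 genes set to the floor of 3 UMIs and no pseudocount, the median was 1.17. In such a median any gene with 0 UMIs in a gestational library ranks lowest. The S phase list (0.79, 17 of 19 higher) stood at 0.60 against the same floor. Il2ra, an interleukin receptor chain (2.4), and AA467197, a gene induced in inflammation (2.39), were higher. Lage3, a tRNA-modifying protein, was 8.29-fold higher at GD14.5 (2.21 to 69.7) and the transcription activator Camta2 5.56-fold (1.46 to 47.2), both with 2 Virgin UMIs. The lowest were Msln (-3.70), the anti-inflammatory cytokine Il10 (-3.01), Scnn1b (-2.67), Glp1r, the incretin receptor of beta cells (-2.50), and Mdm1 (-2.38), of which Glp1r and Mdm1 are also expressed in beta cells. Macrophage activation genes stood at -0.03 (11 of 22 higher), early response genes at 0.18 (15 of 22), interferon at 0.11 (15 of 25), the prolactin list at 0.05 (6 of 11) and cholesterol synthesis at -0.55 (3 of 12). MHC class I (0.50, 11 of 12), oxidative phosphorylation (0.28, 30 of 31) and REG genes (3.37, 5 of 5) were higher.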

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

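The smallest log2 change that counted for this part, 0.1, was set only after the results were seen, and no tests were run here. Hbegf, Egfr, Kmt5a, Prlr, Tph1, Tph2, Ins1, Ins2 and Mki67 were examined in beta cells for a change with opposite sides at different stages, each beyond its counting interval, and Prlr and Ins1 showed one. Prlr, the prolactin receptor, was lower than Virgin at GD6.5, at -0.70 on the log2 scale, and higher in the other 4 libraries, at 1.11, 0.73, 0.15 and 0.59. Ins1, an insulin gene, was lower at GD6.5, at -0.30, and higher in the other 4, at 0.32, 0.21, 0.21 and 0.50. Outside that set, the prolactin-induced gene Cish was also lower at GD6.5, at -0.52, and higher in the other 4 libraries, at 1.5 to 2.09. The difference between GD6.5 and the later libraries was not tested, since each stage has 1 library. Scaling moved the median beta cell gene upward at GD6.5, by 0.17, and against the median-of-ratios scale both genes stood lower still, Prlr at -0.87 and Ins1 at -0.47. No biological explanation was tested, and stage and batch remain open.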

How the results depend on the processing

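The tests under Scrublet's automatic thresholds, in the cluster led by G2/M genes, without GD18.5 and without cells that held a pericyte UMI were chosen only after the results were seen. No paired analysis was possible because each group has 1 library and groups share fewer than 2 replicate numbers. Where a value moved or reversed, the cause was not tested unless stated.

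Of the values that answer a comparison, 23 of 25 for genes, 72 of 85 for lists and 98 of 114 for shares and relations stayed within their intervals and calls. Of the other values, 2072 of 3611 for named genes, 1166 of 1228 for lists and 375 of 456 for shares did. Among those, 14 gene values and 7 list values reversed, and the rest moved in size only. Under all alternatives run, the cycling share of beta cells lay between 0.22% and 0.33% in Virgin, 0.74% and 1.09% at GD6.5, 2.63% and 4.26% at GD10.5, 4.65% and 6.13% at GD14.5, 2.44% and 3.50% at GD18.5, and 1.45% and 2.27% at Pp4. The value of 2.63% was that with at least 3 G2/M genes. The prolactin list at GD6.5 lay between -0.10 and 0.10, and endothelial Hbegf between -0.39 and -0.20. At the other stages the size of the prolactin list varied more. It lay between 0.56 and 1.23 at GD10.5, 1.20 and 2.10 at GD14.5, 1.26 and 1.55 at GD18.5, and 0.59 and 1.68 at Pp4.

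The beta share of Virgin was 64.5% with doublets kept and 64.5% under the automatic thresholds. Under the looser filter (200 genes, no mitochondrial limit, clustered again) it was 23.5% at GD6.5, 26.2% at GD14.5 and 15.5% at Pp4. Under the stricter filter it was 25.9% at GD10.5 and 24.8% at Pp4. It was 23.7% at GD14.5 with doublets kept. At Leiden resolution 2 it was 23.3%, 22.6%, 22.0%, 18.5% and 15.7% from GD6.5 to Pp4.

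The G2/M list in beta cells from GD6.5 to Pp4 stood at 0.53, 1.24, 2.22, 1.39 and 1.05 with a pseudocount of 5 CPM, which by construction shrinks genes of low level. With no minimum level for members, which adds genes of low level, it stood at 1.06, 2.11, 3.2, 2.17 and 1.73. Without hormone genes in the total it stood at 2.96 at GD10.5, 4.01 at GD14.5 and 2.86 at Pp4.

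Without hormone genes in the total, Egfr in beta cells stood at -0.39 and Kmt5a at 0.12 in the gestational mean. The correlation of Egfr with cycling was -0.903 under the looser filter (exact permutation p adjusted 0.0583, n = 6) and -0.760 without hormone genes (exact permutation p adjusted 0.258, n = 6), against 0.0208 to 0.0458 under the other alternatives.

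Reversed without hormone genes were Ivd at GD6.5 (-0.0045), Socs2 at GD6.5 (-0.10), Stat5b in the gestational mean (-0.023), Ucn3 at Pp4 (0.025), H4K20 methylation at GD6.5 (-0.029) and Pp4 (0.052), oxidative phosphorylation at GD6.5 (-0.080) and the mitochondrially encoded list at GD6.5 (-0.011). Reversed with median-of-ratios size factors were H2-D1 at Pp4 (0.0070), Ins2 at GD10.5 (0.048), Socs2 at GD6.5 (-0.061), Ucn3 at Pp4 (0.043), H4K20 methylation at Pp4 (0.069) and oxidative phosphorylation at GD6.5 (-0.038). Reversed under the looser filter were Ins2 at Pp4 (-0.024) and the mitochondrially encoded list at GD14.5 (0.024), and with doublets kept Ins2 at Pp4 (-0.0017). Reversed at resolution 2 were Slc2a2 at GD10.5 (-0.0057) and, in endothelial cells, Lyve1 (0.53), Pld5 (0.10) and Stab2 (0.28). Depth limits genes near the floor, such as Tph1 in Virgin, to wide ratios.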

Other observations

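The clock gene list and its tests, the comparison of cycling with other beta cells, the test of Hbegf in pericytes and the test of scaling were chosen only after the results were seen. Clock genes differed between libraries in all 5 classes, and not in the same way. Dbp, Tef, Nr1d1, Nr1d2 and Per3 are switched on by the activating clock protein that Arntl encodes, and their peak lies opposite to that of Arntl. In alpha cells Dbp stood at 45.5 CPM in Virgin and 6.27, 9.87, 36.1, 5.02 and 9.26 CPM from GD6.5 to Pp4, while Arntl stood at 6.72 CPM in Virgin and 28.9, 27.2, 8.05, 27.8 and 29.9 CPM. Endothelial cells moved as alpha cells did, with Dbp at 121 CPM in Virgin and 6.33, 7.30, 94.6, 6.25 and 7.40 CPM. In delta cells Arntl was lower than in Virgin, at 28.3 CPM in Virgin and 6.25, 10.2, 4.92, 6.62 and 13.1 CPM. Dbp stood at 48.1 CPM in Virgin and 82.5, 37.3, 109, 62.9 and 62.2 CPM, and the Dbp arm at -0.28 at GD10.5 and 0.06 at GD18.5, so the opposite order rested on the Arntl arm at these stages. The difference between the Dbp arm and the Arntl arm at GD6.5 was 2.34 on the log2 scale in delta cells, 0.28 in beta cells, -0.37 in macrophages, -1.74 in alpha cells and -2.82 in endothelial cells.

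Cycling beta cells were compared with the other beta cells of the same library, which holds stage and batch constant. Kmt5a was higher in cycling cells in all 6 libraries, with ratios of 3.88 in Virgin (95% interval 2.68 to 5.43), 4.93 at GD6.5, 3.14 at GD10.5, 5.08 at GD14.5, 4.42 at GD18.5 and 2.71 at Pp4. Cdkn2c, an inhibitor of the D cyclin kinases, was higher by 10.7-fold to 29.8-fold, and Ezh2, which methylates histone H3, by 7.17-fold to 33.1-fold. Cdkn1b, another cyclin kinase inhibitor, was higher by 1.74-fold to 2.41-fold. Ccnd2 was lower in cycling cells in Virgin and gestation, with ratios of 0.48 to 0.68, but at Pp4 its interval included 1 (0.94, 0.83 to 1.05). The glucose transporter Slc2a2 was lower in all 6 libraries, with ratios of 0.45 to 0.62. Egfr had no common side within libraries. Its ratio was 1.90 in Virgin (1.30 to 2.69), 0.65 at GD18.5 (0.46 to 0.90) and 0.57 at Pp4 (0.31 to 0.96). Its intervals included 1 at GD6.5 (0.88), GD10.5 (0.92) and GD14.5 (0.84). The Virgin ratio rests on 32 Egfr UMIs of 14 cycling cells and that of Pp4 on 14 UMIs of 8 cells, so neither side is firm. Tph1 also had no common side within libraries. Its ratio was 0.21 at GD10.5 (0.09 to 0.42), 1.27 at GD14.5 (1.04 to 1.53) and 0.75 at GD18.5 (0.43 to 1.24). At Pp4 cycling cells held 0 Tph1 UMIs, and Virgin and GD6.5 held too few for a ratio. Prlr was lower in cycling cells at GD10.5 (0.86), GD14.5 (0.89) and GD18.5 (0.84), and its intervals included 1 in the other libraries. In the non-cycling cells Kmt5a stood at 16.4 CPM in Virgin, 19.8, 18.2, 14.6 and 14.7 CPM in gestation and 17.4 CPM at Pp4. In CPM it thus lay above Virgin at GD6.5 and GD10.5 and below it at GD14.5 and GD18.5. For this set neither an interval against Virgin nor the other scalings were computed. The direction at GD6.5 is not firm, since scaling alone moved the median beta cell gene there by 0.17 on the log2 scale. Cycling cells held more UMIs, with medians of 29912 against 21459 at GD14.5, and 14, 18, 89, 124, 57 and 8 of them were found from Virgin to Pp4. Intervals cover counting error of the pooled UMIs only and hold no variation between cells, and no cause was tested.

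The CPM of endothelial Hbegf was not above Virgin in gestation. The share of endothelial cells with an Hbegf UMI after thinning was above Virgin at GD10.5 and GD14.5 and below it at GD6.5 and GD18.5. Pericytes within the Virgin endothelial class are argued against as its source, since Hbegf in Virgin pericytes was 0.149 of its level in Virgin endothelial cells (95% interval 0.0785 to 0.256). Dissociation stress of the Virgin endothelial cells, which could raise Hbegf as an early response gene, cannot be told apart, because the median of the early response list in these cells was -0.033 with an interval from -0.21 to 0.013. The stage of pregnancy and the batch stay open, and neither was tested.

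Early response and heat shock genes were lower than Virgin in beta cells. For the gestational mean, a handling difference that acts on all classes alike is argued against, as 1 of the 4 other classes, delta cells, had an interval below 0. At Pp4 such a difference stays open, since the list was also below 0 in alpha (-0.44, -0.57 to -0.31), endothelial (-0.44, -0.63 to -0.18) and delta cells (-0.57), though not in macrophages (0.20, -0.04 to 0.38). At GD10.5 alpha cells were below 0 as well (-0.19, -0.42 to -0.08). Scaling by the total count is argued against as well, since the median stayed at -1.01 (-1.32 to -0.72) with median-of-ratios size factors. Handling that acts on beta and delta cells alone, a lower activity of these cells in gestation, and batch may each contribute and were not tested.

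A difference in the hour of the day, with the clocks of all classes in phase, is argued against for the clock genes, as the difference between the arms had the same sign in all 5 classes in 0 of 5 libraries. At GD10.5, GD18.5 and Pp4 delta cells alone broke the agreement. At GD10.5 the difference was 1.01 in delta cells, against -0.95 in beta, -1.40 in alpha, -2.68 in endothelial cells and -0.68 in macrophages. A difference in hour that the classes other than delta share thus stays open at these stages. Without Per1 and Per2, which are early response genes, 24 of 25 pairs of class and library kept the sign and at least 0.5 of the size of the difference. The Dbp arm is a median of 9 genes, or 6 in macrophages, which the loss of a pair of genes moves little. The differences thus did not rest on these genes alone, but this cannot decide whether handling stress acted on clock genes. Clocks that run at different phases in different classes, sampled at different hours, might give the pattern and stay open, as do batch and stage, none of which was tested.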
